A study of Mus musculus with 6 samples.

How the data were processed

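Total RNA from 6 samples of sorted mouse HSCs was labelled with biotin and hybridized to 1-colour Affymetrix whole-transcript arrays, per the labels' protocols. The deposited values are log2 signals per probe set, already normalized between arrays by the authors: the scale was read from the values, which ran from 1.62 to 13.0, and the 6 sorted columns lay within 0.117 of their mean. The submitters' processing notes name Partek, with no version or role. The background correction, the summarisation, any filter on dim probe sets and the genome build are not given in the sources used here, and no coordinates are given for that reason. Normalization between arrays sets the overall level of each array alike, so a change shared by most genes would not be seen, and dim signals compress fold changes.

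The table held 27037 rows. The platform annotation gave 1 gene symbol for 23521 of them, several for 1820 and none for 1696. Symbols were updated through the gene ID in a gene table of the mouse assembly GRCm38.p6, used for names only, which matched 23328 of the rows with 1 symbol. Rows with several symbols or none were left out of the gene-level tests. For the 1082 genes with over 1 probe set, the probe set with the highest mean over the 6 samples was used, which left 22180 genes. Of 425 members of the gene lists, 384 were measured and 41 were not analysed here, 21 of these because they shared a probe set with another gene. Mpl and Stat1 were among those not analysed here. Probe sets of near-identical paralogs, as in the Oas, immunity-related GTPase, Ifi200, Trim30 and interferon alpha families, may share signal, and the values of single members are uncertain.

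Samples were grouped by their titles into 3 with TPO and 3 without. No array date, slide or other batch was analysed here. Correlations between samples across probe sets lay between 0.957 and 0.981, and at most 39 rows held the same value in any pair of samples. The labels say that samples with the same number came from the same pool of HSCs. The deviations from the group means correlated across genes at 0.295, 0.261 and 0.146 in pools 2, 3 and 4, so the numbers pair the samples. The unpaired fit was the main one, and the fit with the pool as a block is given where it changed the call of a list, the call of a named gene over all genes, or the count of list members that passed. The samples of a group came from separate pools of mice.

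Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom and 3.54 prior ones), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are log2 values with TPO minus without, each with limma's moderated standard error, and SDs are between samples of a group. With 3 samples against 3, an exact permutation test of a single value cannot give a p under 0.1, so single values were not tested that way. Shifts of 19 gene lists were tested with limma's camera, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; an estimated correlation and limma's fry were alternatives. Members passing within a list were counted after adjustment over the list alone as well as over all genes. The lists, tests, alternatives and the rule for naming genes were chosen before the data were examined, apart from those described below or in the closing section as added or chosen afterwards.

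The rule named, among genes past the threshold whose groups did not overlap, up to 15 with the largest rise and up to 15 with the largest fall, without predicted or small RNA symbols. A direction with fewer than 10 was filled to 10 by the smallest unadjusted p. It also named up to 4 members of each list with the smallest p, list members past the threshold, and always Mpl, Ier3, Cdkn1a, Socs3, Cish, Stat1, Irf7, Isg15, Egr1 and Fos. Genes with predicted symbols past the threshold, Ccnd1, and list members that passed in only 1 of the unpaired and paired fits were named in addition, after their values were seen, to complete counts. Lists of macrophage and dendritic cell markers, of interferon ligands and of interferon receptors were added after a first look at the gene table and before their own tests.

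The procedure was tested on simulated data for the comparison with TPO against without, over 22180 genes of which 200 were changed. It recovered 62.7% of changes of 1 log2 unit, 86.6% of changes of 2 and 95.5% of changes of 3, called 7 unchanged genes, and found the 1 list that had been shifted. Differences between pools entered the simulation only as independent spread of single genes, and each gene's estimated spread was taken as its true one. The simulated data gave 170 calls against 16 in the real data, and more calls loosen the adjusted threshold. The recovery rates therefore cannot be carried over to the real data, where Trim30c, at a log2 difference of 3.52, did not pass unpaired. The list was shifted by 1 log2 unit in every member, and its genes were drawn independently. Finding it therefore does not show how the list test performs on lists whose members are correlated. A gene that did not pass was not shown to be unchanged. Alternatives were the pool as a block, leaving out each sample or pool, leaving out the dimmest 25% or 50% of genes, quantile normalization, median centring, a trended prior, array weights, the mean over a gene's probe sets, every row of the table, and other thresholds. An alternative pseudocount did not apply, since the values were already log2. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.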

Results

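Gene expression was measured in mouse hematopoietic stem cells (HSCs), the bone marrow cells from which all blood lineages arise, after exposure to thrombopoietin (TPO) and ionizing radiation. TPO is the cytokine ligand of the receptor Mpl and acts on HSCs as well as on megakaryocytes. The cells had been sorted as lineage-negative, Sca+, Kit+, CD34-negative and Flk2-negative, 10000 cells per sample, and each pool combined 8 to 10 mice of the C57BL/6 strain. They were cultured for 45 min with Flt3 ligand, interleukin-3, interleukin-6 and stem cell factor, with or without TPO at 50 ng/ml, then received 2 Gy, and RNA was taken 45 min later. Each group held 3 samples, and pools 2, 3 and 4 gave replicates 1, 2 and 3 of both groups. The 6 samples were each measured on an Affymetrix whole-transcript array, whose median log2 signals lay between 5.13 and 5.21. The number of arrays limits the precision. No unirradiated sample was analysed here, so the comparison addresses what TPO changed in irradiated HSCs and not what irradiation itself changed. The titles of the samples without TPO could also be read as lacking irradiation. The growth protocol describes irradiation in the presence or absence of TPO, and both groups are taken as irradiated on that basis.

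Genes that interferons are known to induce rose with TPO, and 5 of the 16 genes past the threshold were on the fixed interferon response list. Mx2, a dynamin-like antiviral GTPase, rose 4.67-fold (log2 difference 2.22 ± 0.12 SE, n = 3 per group, limma adjusted p = 0.00334). Oasl2, of the oligoadenylate synthetase family, rose 4.70-fold, Ifit1, which binds viral RNA, 4.21-fold, and Irf7, a transcription factor that drives interferon genes, 3.22-fold, each with an adjusted p of 0.0184. Igtp and Iigp1, GTPases of the immunity-related family that act on vacuoles holding pathogens, rose 5.02-fold and 7.48-fold (adjusted p = 0.0206 and 0.0372). Among the 13 genes with an established symbol, those of secreted proteins had the largest folds, namely Timp1, an inhibitor of metalloproteinases, at 12.6-fold, the cytokine Il24 at 9.09-fold and the chemokine Cxcl9 at 8.68-fold.

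In all, 16 of 22180 genes passed an adjusted p of 0.05 in limma, and all 16 were higher with TPO. No gene passed as lower, where the smallest adjusted p was 0.0786. At an unadjusted p under 0.05 limma gave 1286 genes, 588 higher and 698 lower. The other splits of the 6 samples into 3 and 3 gave 640 to 1596 genes by the same measure. The 1286 therefore lie within what other groupings gave. In each of the 16, every sample with TPO lay above every sample without it. A gene that passes with 3 samples against 3 is likely to be separated, so this is no further support. Over all genes 10.1% showed such a separation in either direction. Chance gives 10% if the 6 samples are exchangeable, which the pairing by pool goes against. The 13 with an established symbol were those above together with Xaf1 (3.78-fold), Tm4sf1 (3.04-fold), Il18rap, a subunit of the interleukin-18 receptor (2.80-fold), and Slfn5 (2.75-fold). The other 3 carried predicted symbols, namely Gm12250 (11.0-fold), Gm4951 (5.59-fold) and Gm12185 (5.22-fold). These 3 are grouped here with Igtp and Iigp1 as immunity-related GTPases. The mean log2 signal of Timp1 was 5.03 ± 0.49 (SD, n = 3) without TPO and 8.69 ± 0.78 (n = 3) with it, and that of Mx2 was 4.64 ± 0.0057 and 6.86 ± 0.0024 by the same measure. Paired by pool, 31 genes passed, 30 of them higher, and 15 of the 16 were among them. Slfn5 was lost with an adjusted p of 0.0557, and Isg15 and Ccl4 were gained among the genes named by the rule. The unpaired count was 0 without the pool 4 sample of either group and without both samples of pool 2, 3 or 4. It was 1 and 5 without the pool 2 sample of the group without and with TPO, 8 without the pool 3 sample of the group without TPO, 27 without the dimmest 50% of genes, 29 with array weights and 10 with every row tested.

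**Figure D1:**
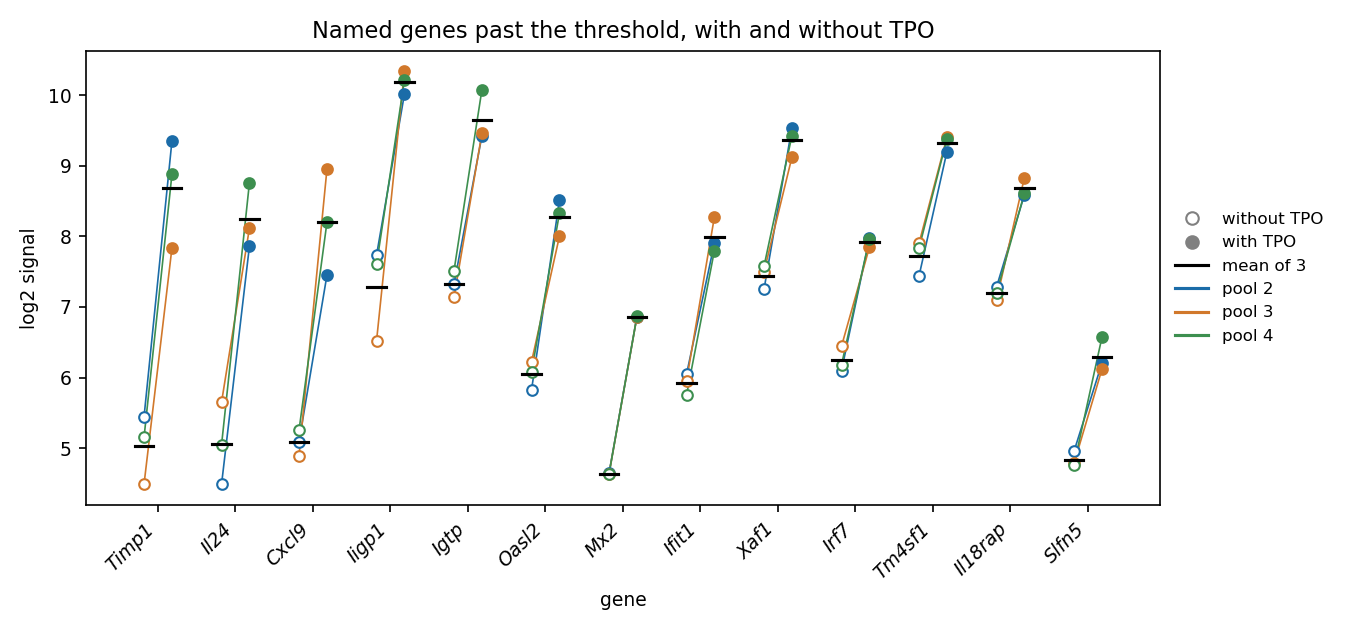
Log2 signal (vertical axis) of the 13 named genes past the threshold, with open circles for samples without TPO and filled circles for samples with it. Lines join the samples of a pool and black bars are means of 3. The rule for naming these genes required the 3 filled circles to lie above the 3 open ones. The means differ by 1.46 (Slfn5) to 3.66 (Timp1) on the log2 scale.

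The genes lower with TPO that had the smallest p did not pass the threshold in limma. Mgat4b, a glycosyltransferase that branches N-glycans, had a log2 difference of -1.31 ± 0.18 (SE, n = 3 per group, adjusted p = 0.0786). Kdsr, an enzyme of sphingolipid synthesis, had -0.90 ± 0.13 (adjusted p = 0.0874), Mylip, a ubiquitin ligase for the LDL receptor, -1.26, and Cdk7, a kinase of the general transcription machinery, -0.75. The others by this rule were Smim24 (-0.87), Slc35b4 (-0.92), Etfdh (-0.73), Sdhaf1 (-0.93), Zswim7 (-0.90) and Prelid2 (-0.95), with adjusted p from 0.161 to 0.253. All 10 were lower with TPO in all 3 pools.

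Of the fixed gene lists, the interferon response list moved furthest. All 40 measured members of 44 were higher with TPO, 35 of them in all 3 pools, and the median log2 difference was 1.02, a 2.02-fold median. Besides Mx2, Oasl2, Ifit1, Irf7 and Xaf1, which passed over all genes tested, Isg15, a ubiquitin-like protein attached to other proteins after interferon, had a log2 difference of 1.69 ± 0.22 (SE, n = 3 per group, adjusted p = 0.0730). Adjusted over the list alone, 33 members rose and 0 fell, against 5 over all genes tested. The median difference was 1.08 in pool 2, 0.879 in pool 3 and 1.13 in pool 4. In limma's camera test against the other genes the list had an adjusted p of 2.74e-57 with the preset correlation of 0.01. With an estimated correlation the adjusted p = 0.0174, and it was the only list that kept its call; with pools paired as well, adjusted p = 0.326. Paired by pool, 8 members passed over all genes tested, with Isg15, Oas2 and Eif2ak2 added, and 32 adjusted over the list alone, with Adar gained and Ifit3 and Ifitm3 lost. Macrophage and dendritic cell markers, measured beside it, had a median log2 difference of 0.0428, and the myeloid list one of 0.0383, with its members Irf8 (1.79), Ctsg (0.62) and Fcgr3 (0.49) higher in all 3 pools.

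**Figure D2:**
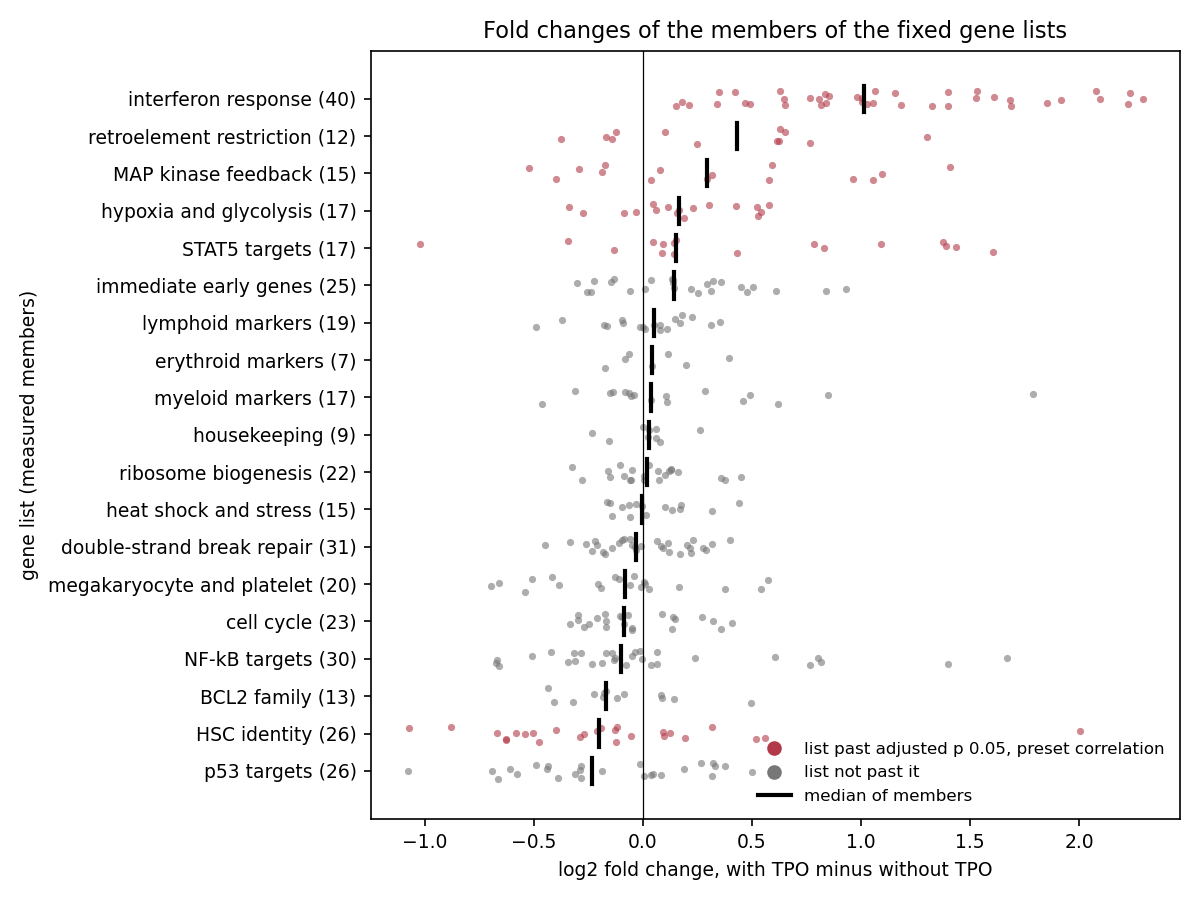
Log2 fold change with TPO minus without (horizontal axis) of every measured member of the 19 fixed gene lists (rows, number of measured members in brackets), with black bars for list medians. Red lists passed the camera test with its preset correlation; only the interferon response list, with all 40 points above 0 and a median of 1.02, also passed with an estimated correlation.

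Targets of STAT5, a transcription factor that Mpl and the interleukin-3 receptor activate through JAK kinases, were higher as a list. Of 17 measured members 14 were higher, with a median log2 difference of 0.15 and a mean of 0.48. Adjusted over the list alone 4 rose and 1 fell, against 0 over all genes tested. The 4 were Gadd45g (2.59-fold), Id1 (2.62-fold), Cish, a feedback inhibitor of cytokine receptors (1.78-fold), and the cyclin gene Ccnd1 (log2 difference 0.78). Bcl6, a transcriptional repressor that STAT5 is known to repress, fell, with a log2 difference of -1.02 ± 0.29 (SE, n = 3 per group). Socs3, another feedback inhibitor, had a log2 difference of 1.60 ± 0.59 that did not pass in the unpaired fit. With pools paired 7 rose and 1 fell adjusted over the list alone, with Osm, Socs1 and Socs3 added. The camera test gave an adjusted p of 0.00024 with the preset correlation. The call was lost with an estimated correlation (adjusted p = 0.263) and with fry (0.322).

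Feedback regulators of the MAP kinase pathway, which growth factor receptors induce to dampen their own signal, were also higher. Of 15 measured members 10 were higher, with a median log2 difference of 0.29. There were 4 members that rose adjusted over the list alone, 0 that fell, and 0 that passed over all genes tested. These were the Sprouty genes Spry2 (2.66-fold) and Spry4 (2.08-fold), the ERK phosphatase gene Dusp6 (1.95-fold) and the Sprouty-related gene Spred1 (1.49-fold). With pools paired 6 rose, with Errfi1 and Dusp5 added. The list's adjusted p was 0.0136 in camera with the preset correlation, and the adjusted p = 0.513 with an estimated correlation. The call was also lost without the pool 2 or pool 4 sample without TPO (adjusted p = 0.255 and 0.111), without the pool 3 or pool 4 sample with TPO (0.111 and 0.0678), without pool 4 (0.197), with array weights (0.0645) and with fry (0.445).

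Immediate early genes, which growth factors and stress induce within minutes, did not pass as a list in the unpaired test. Of 25 measured members 18 were higher, the median log2 difference was 0.14, and adjusted over the list alone 0 passed, as over all genes tested. Atf3 had a log2 difference of 0.93 ± 0.56, Egr2 of 0.84 ± 0.37, Egr1 of 0.61 ± 0.40 and Fos of 0.29 ± 0.52 (SE, n = 3 per group). Klf6 had 0.51 and Arc 0.25. With pools paired, 2 members passed adjusted over the list alone, Egr2 and Atf3. The level of the list differed more between pools than between groups. Set against its mean over the 6 samples, the list stood at 0.53 and 0.64 log2 units in the pool 3 samples without and with TPO, at -0.43 and -0.31 in those of pool 2, and at -0.39 and -0.04 in those of pool 4. The camera adjusted p was 0.0637 unpaired and 0.00534 with pools paired; with an estimated correlation the adjusted p = 0.713 unpaired and 0.438 paired. Without the pool 2 sample with TPO the unpaired camera value was 0.000975, and without the pool 3 sample without TPO 1.06e-06. With 1 sample of a pool left out, the groups no longer hold the same pools. These 2 values therefore mix the pool differences with TPO. Without pool 2 or pool 3 the unpaired value was 0.0405 and 0.00831, and without the dimmest 25% or 50% of genes it was 0.0466 and 0.0460.

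**Figure D3:**
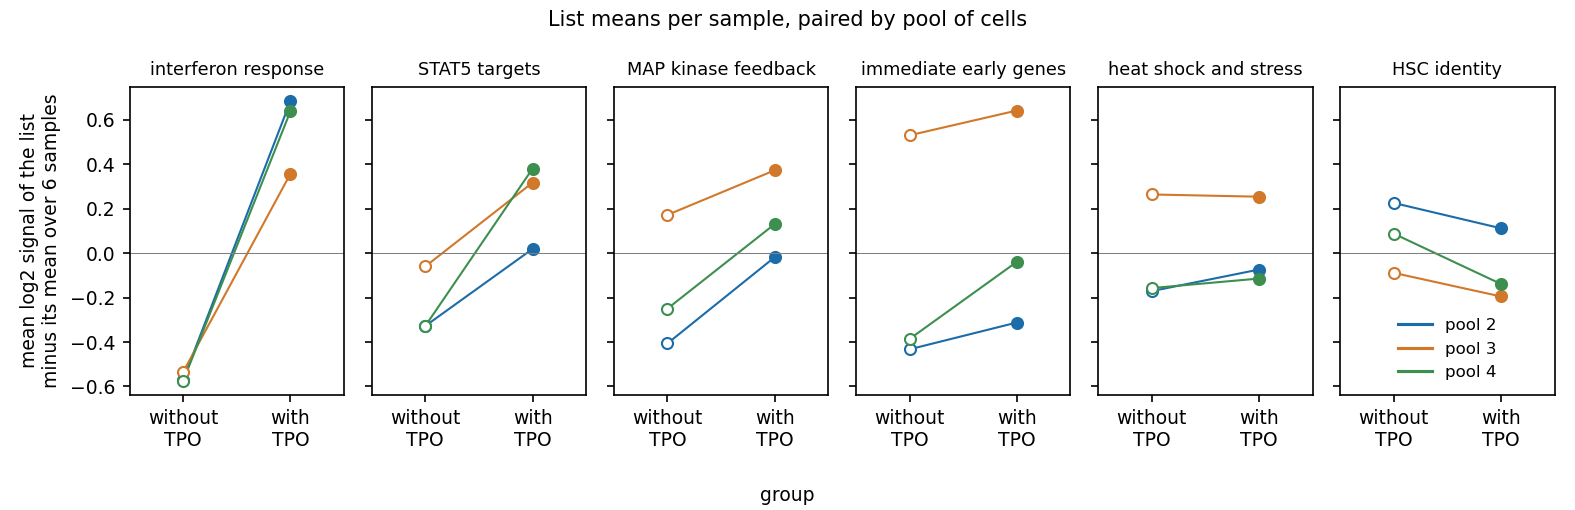
Mean log2 signal of 6 gene lists in each sample minus the mean over the 6 samples (vertical axis), without (open) and with TPO (filled), with a line for each pool. The interferon response list separates the groups in every pool, while the immediate early list is highest in both samples of pool 3, at 0.53 and 0.64.

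Targets of NF-kB showed no shared direction. Of 30 measured members 20 were lower, the median log2 difference was -0.10, the mean was 0.04 with the same upward sign as the test, and the camera adjusted p was 0.935. Adjusted over the list alone 0 passed, as over all genes tested. The members with the smallest p were Irf1 (0.82), the chemokine genes Ccl4 (1.67) and Cxcl10 (1.40), and Ptgs2, the inducible cyclooxygenase (0.80), given as log2 differences, and Irf1 and Cxcl10 are also on the interferon list. With pools paired, Ccl4 passed over all genes (adjusted p = 0.0269), and adjusted over the list alone 5 were higher (Ccl4, Cxcl10, Ptgs2, Irf1 and Cxcl2) and 2 lower (Gadd45b and Cd83). Ier3, a stress-inducible gene of this list, had a log2 difference of -0.13 ± 0.14 (SE, n = 3 per group, adjusted p = 1.000 in limma).

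The list of genes that restrict retroelements was higher, with a median log2 difference of 0.43 over 12 measured members, 8 of them higher in all 3 pools. With p adjusted over the list alone 2 rose and 0 fell, against 0 over all genes tested. The 2 were Isg20, an exonuclease for single-stranded RNA (2.47-fold), and Bst2, a membrane tether of budding virions (1.70-fold). Samhd1 (1.57-fold) and Mov10 (1.53-fold) did not pass unpaired, and with pools paired Samhd1 made a count of 3. The camera adjusted p was 0.0053 with the preset correlation, and the adjusted p = 0.472 with an estimated correlation. Without the 3 members that the interferon list also holds it was 0.245, and the median over the other 9 was 0.103. It was 0.0855 without the pool 4 sample with TPO, 0.0619 without pool 4 and 0.445 with fry.

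Genes of hypoxia and glycolysis were higher as a list by a smaller amount. The median log2 difference was 0.17 over 17 measured members, 13 of them higher. Hif1a, the oxygen-regulated transcription factor, had a log2 difference of 0.53, and the glycolytic genes Hk2, Pfkp and Ldha had 0.52, 0.54 and 0.58. No member passed adjusted over the list alone, a count of 0, as over all genes tested. The camera adjusted p was 0.0123 with the preset correlation, and the adjusted p = 0.472 with an estimated correlation. The call was lost without the pool 2 or pool 4 sample without TPO (0.255 and 0.111), without the pool 4 sample with TPO (0.0855), without pool 2 or pool 4 (0.0866 and 0.252) and with fry (0.445).

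Genes that mark HSC identity were lower as a list, with 18 of 26 measured members lower and a median log2 difference of -0.20. Adjusted over the list alone 2 fell and 1 rose, against 0 over all genes tested. Robo4, a receptor that helps HSCs lodge in the marrow, had a log2 difference of -1.07 ± 0.21 and Txnip, an inhibitor of thioredoxin, -0.88 ± 0.23 (SE, n = 3 per group). Slamf1, which encodes the HSC surface marker CD150, went the other way at 4.01-fold, a log2 difference of 2.00 ± 0.34. Tal1, a transcription factor of blood stem cells, had -0.63 and did not pass. With pools paired 3 fell, with Hlf added, and 1 rose. The camera adjusted p was 0.0246 with the preset correlation, and the adjusted p = 0.513 with an estimated correlation. The call was lost without the pool 2 or pool 4 sample without TPO (0.305 and 0.111), without the pool 3 or pool 4 sample with TPO (0.301 and 0.104), without pool 4 (0.252), without the dimmest 50% of genes (0.107), with quantile normalization (0.0733), with array weights (0.0886) and with fry (0.445).

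Targets of p53, the main transcriptional responder to DNA damage, did not pass as a list. Of 26 measured members 15 were lower with TPO, with a median log2 difference of -0.24 and a camera adjusted p of 0.155; without pool 3 it was 0.0403. The count was 0 both adjusted over the list alone and over all genes tested. Trp53inp1 had a log2 difference of -1.08 ± 0.23, Ei24 -0.69 ± 0.19, Sesn1 -0.66 ± 0.22 and Bbc3, which encodes the apoptosis inducer PUMA, -0.43 ± 0.17 (SE, n = 3 per group). With pools paired, Trp53inp1, Ei24 and Sesn1 passed adjusted over the list alone. Cdkn1a, the p53-induced cell cycle inhibitor p21, had a log2 difference of 0.19 ± 0.15. Its mean log2 signal was 11.6 without TPO and 11.8 with it. Double-strand break repair genes had a median of -0.03 over 31 measured members, a mean of 0.0043 and an upward test (camera adjusted p = 0.632; median 0.0077 after quantile normalization), with Xrcc5 at 0.40, Bard1 at 0.32, Blm at -0.45 and Rnf168 at -0.26. The BCL2 family had a median of -0.17 over 13 (adjusted p = 0.245), with Bcl2 itself at 0.50, Bad at -0.23 and Bmf at -0.41. In both lists 0 members passed adjusted over the list alone, and 0 over all genes tested.

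The lists of other cell types, growth, stress and housekeeping did not pass in the unpaired camera test with all samples. Megakaryocyte and platelet genes, the lineage that TPO expands, had a median log2 difference of -0.08 over 20 measured members (camera adjusted p = 0.378), with the platelet chemokine gene Ppbp at 0.57, Cd9 at -0.70, Nfe2 at -0.66 and Zfpm1 at -0.42. Erythroid markers had a median of 0.04 over 7 (0.488), with Car2 at 0.40, Slc4a1 at 0.20, Epor at 0.11 and Car1 at -0.17, and lymphoid markers one of 0.05 over 19 (0.395), with Dntt at 0.31, Rag2 at 0.35, Cd3e at 0.18 and Ighm at -0.49. Myeloid markers had a median of 0.04 over 17 (0.245), in which Irf8, a transcription factor of monocytes and dendritic cells, had a log2 difference of 1.79 ± 0.57 (SE, n = 3 per group), Ctsg 0.62, Fcgr3 0.49 and Csf3r -0.31. Ribosome biogenesis genes had a median of 0.02 over 22 (0.378), with Odc1 at 0.45, Nop58 at 0.38, Nop16 at 0.36 and Wdr12 at -0.33, and cell cycle genes -0.09 over 23 (0.804), with Plk1 at 0.41, Cdk1 at 0.36, Bub1 at 0.32 and Mcm3 at -0.30. Heat shock and stress genes had a median of -0.0028 over 15 (0.582), a mean of 0.04 and an upward test (median 0.0084 after median centring), with Trib3 at 0.44, Dnajb1 at 0.32, Hspa8 at 0.10 and Bag3 at -0.14, and housekeeping genes 0.03 over 9 (0.763), with Polr2a at 0.26, Hprt at 0.08, Sdha at -0.16 and Gusb at -0.24. In these 8 lists 0 members passed adjusted over the list alone, and 0 over all genes tested. Without the pool 3 sample with TPO the ribosome biogenesis list had 0.00117, and without the pool 3 sample without TPO the myeloid list had 0.0379. In both cases the groups no longer held the same pools, so these values mix pool with TPO. Without pool 3 the 2 lists had 0.00926 and 0.0313.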

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

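Outside the gene-level comparison lay 4857 rows of the table, namely probe sets with several gene symbols, with none, or second probe sets of a gene. When every row was tested together in limma, 1 of these rows passed an adjusted p of 0.05. It was a probe set annotated to 2 genes, Olfr56 and the immunity-related GTPase gene Ifi47. The log2 difference was 1.40 ± 0.14 (SE, n = 3 per group, limma adjusted p = 0.0461), with higher signal with TPO. Which of its genes gave the signal is not resolved by the array. At an unadjusted p under 0.05 these rows gave 266, where chance gives 242.85.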

How the results depend on the processing

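The tests with a pool left out in the paired fit, the paired test of interferon ligands, the retroelement list without interferon members and the interferon list without members of other lists were chosen after seeing the data. The interferon list kept its call under every alternative run singly, with adjusted p from 6.93e-60 to 0.0174, and lost it only with pools paired and an estimated correlation together (0.326). The 16 genes past the threshold, all higher, became 31 (30 higher, 1 lower) with the pool as a block, 27 without the dimmest 50% of genes (fewer genes tested), 29 with array weights, 10 with every row tested, 42 (40 higher, 2 lower) at an adjusted p under 0.1, and 608 (334 higher, 274 lower) at an unadjusted p under 0.05 with a fold of 1.5. Without the dimmest 25% the count was 17, with quantile normalization 18, with median centring 15. It ran from 0 to 14 as single samples or pools were left out (fewer samples). In the paired fit, leaving out pool 2, 3 or 4 gave 42 (40 higher, 2 lower), 88 (75 higher, 13 lower) and 11 (10 higher, 1 lower). With 2 pools left, these counts rest on few residual degrees of freedom, and why they differ was not tested. The gene lost to pairing was Slfn5, and the block changed no other call of a list, call of a named gene over all genes, or count of list members than those given with the results.

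The 6 lists past the threshold became 1 with an estimated correlation and 1 with fry, and 2 to 10 as samples or pools were left out. With an estimated correlation the adjusted p was 0.513 for MAP kinase feedback and for HSC identity, 0.263 for STAT5 targets, and 0.472 for retroelement restriction and for hypoxia and glycolysis; with fry it was 0.322 for STAT5 targets and 0.445 for the other 4. Immediate early genes had 0.00534 with the pool as a block, 0.0466 without the dimmest 25% and 0.0460 without the dimmest 50%. With an estimated correlation in camera that list had 0.713 unpaired and 0.438 with the pool as a block. HSC identity had 0.107 without the dimmest 50%, 0.0733 with quantile normalization and 0.0886 with array weights. MAP kinase feedback had 0.0645 with array weights, and retroelement restriction 0.245 without interferon members. As samples or pools were left out, the adjusted p ran from 1.06e-06 to 0.717 for immediate early genes, 0.000107 to 0.255 for MAP kinase feedback, 7.84e-05 to 0.0855 for retroelement restriction, 0.000200 to 0.255 for hypoxia and glycolysis, 0.000600 to 0.305 for HSC identity, 0.00117 to 0.949 for ribosome biogenesis, 0.0313 to 0.570 for myeloid markers and 0.0403 to 0.672 for p53 targets. With a single sample left out, the groups no longer held the same pools, so those values mix pool with TPO. Apart from this and from fewer genes or samples, the cause was not tested. Of 1692 comparisons of 100 named genes, 1585 stayed on the same side of the threshold. In 103 the gene was no longer past it, in 4 it passed anew, and 0 reversed. A sign change of a value past the threshold under neither setting was not counted as a reversal and is among the 1585. Most named genes were not past the threshold in the main fit and had no call to lose. All 103 losses fell on the 13 genes with an established symbol that were past it. Each of these was past it in only 6 (Slfn5) to 12 (Mx2) of 17 alternatives. Signal over background was not analysed here, so a bound for dim genes cannot be given.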

Other observations

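The families in this paragraph were chosen after their values were seen. The rise of immunity-related GTPases extended over most of the family. Of 11 measured members 9 were higher with TPO in all 3 pools, with a median log2 difference of 2.32, and 5 passed over all genes tested (7 with pools paired). Irgm1 and Irgm2, regulators of the other family members, had log2 differences of 2.11 ± 0.28 and 2.04 ± 0.25 (SE, n = 3 per group), while Irgq had -0.11 ± 0.17 and Irgc1 -0.04 ± 0.17. Guanylate-binding proteins, the related family of larger interferon-inducible GTPases, had a median of 0.38 over 10 members, and 0 passed in limma with or without pairing; 4 had an unadjusted p under 0.05. The difference between these families was not tested. The Trim30 cluster had a median of 1.51 over 5 members, with Trim30c at 3.52 ± 0.49, with an adjusted p of 0.0786 unpaired and 0.0089 with pools paired. The IFI200 family of DNA sensors had a median of 0.53 over 11, with Ifi204 at 2.55 ± 0.37 (adjusted p = 0.0901 unpaired and 0.0089 with pools paired). Ifi204 was dim, with a mean log2 signal of 2.28 without TPO and 4.82 with it, both below the lowest array median of 5.13. Schlafen genes had a median of 0.30 over 9, PARP genes 0.09 over 11, CXC chemokines 0.28 over 15 and interleukins 0.16 over 33. Adjusted over each family alone, 9 immunity-related GTPases, 0 guanylate-binding proteins, 4 of the Trim30 cluster (Trim30a, b, c and d), 4 of the IFI200 family (Ifi203-ps, Ifi204, Ifi213 and Mndal), 3 Schlafen genes (Slfn2, Slfn5 and Slfn8), 3 PARP genes (Parp9, Parp12 and Parp14), 5 CXC chemokines (Cxcl3, Cxcl5, Cxcl9, Cxcl10 and Cxcl11) and 3 interleukins (Il10, Il24 and Il27) rose, with Cxcl3 at 3.76 ± 1.03, Cxcl9 at 3.12 ± 0.35, Il24 at 3.18 ± 0.34 and Il10 at 1.71 ± 0.39. Over all genes tested in the unpaired fit, 1 CXC chemokine (Cxcl9), 1 interleukin (Il24) and 1 Schlafen gene (Slfn5) passed. In the Trim30 cluster, the IFI200 family and the PARP genes 0 passed in that fit. Since the families were chosen after their values were seen, the counts adjusted over a family alone are descriptive and no test of the family. The median of each family kept its sign after quantile normalization and after median centring. Members of several of these families are near-identical paralogs, and single values are uncertain.

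The 6 measured genes of interferon receptor subunits had log2 differences below 0, as values with no test of the list. The subunit genes Ifnar1 and Ifnar2 had log2 differences of -0.25 ± 0.20 and -0.18 ± 0.23 (SE, n = 3 per group), Ifngr1 and Ifngr2 -0.45 ± 0.16 and -0.46 ± 0.35, Ifnlr1 -0.02 ± 0.18 and Il10rb -0.31 ± 0.18. The only gene past the threshold as lower with pools paired was Tlcd1, at -1.82 ± 0.49 unpaired (adjusted p = 0.516 unpaired and 0.0269 paired).

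The test of whether a single pool carried the interferon rise and the paired test of interferon ligands were chosen after the results were seen. Macrophages or dendritic cells in the samples with TPO would bring their own abundant transcripts, which the lineage-negative sort is meant to remove. Over 21 of 22 listed markers the median log2 difference was 0.0428, with an upper 95% limit of 0.0700. That lay under 0.254, the bound set beforehand at 25% of the interferon median. The limit was taken over the marker genes and holds no spread between samples, so it cannot exclude such cells. Each pool of sorted HSCs gave a sample to both groups, so such cells in a pool could have entered both. Whether they were shared unevenly was not tested. In limma, the highest upper 95% limit of a single marker was 0.878 (Tyrobp), above 0.254 and below the interferon median of 1.02. Among bright markers, Lyz2 had a mean log2 signal of 9.19 with TPO and 9.23 without, and Fcer1g 8.94 and 8.75. C1qc was dim, at 3.91 in both groups. Of the 21 markers 13 were higher, with Ctss, at 0.33, and Itgax, at 0.26, higher in all 3 pools. Off this list, the myeloid members Irf8, at 1.79 (pools 3.00, 0.74 and 1.62), and Fcgr3, at 0.49, were also higher in all 3 pools. Flt3 is also on the lymphoid list, and Csf1r and Lyz2 are on the myeloid list. An intensity-dependent bias of the values is argued against by 0% of 10000 random lists matched on signal reaching the interferon median of 1.02 (highest 0.191), and 1 pool of cells carrying the rise by a smallest pool median that was 0.778 of the largest. Also open is whether the cells made interferon themselves. Of 20 measured ligand genes the highest log2 difference was 1.06 (Ifna4, higher in all 3 pools). In limma its adjusted p over the ligands was 0.410 unpaired and 0.0296 with pools paired, so Ifna4 met the mark set beforehand in the paired fit alone. Ifnk, Ifna6, Ifnb1 and Ifnl2 were also higher in all 3 pools, while Ifng, Ifna11, Ifna15 and Gm13271 were lower in all 3. The median over the ligand genes was -0.0034. The largest upper limit of a ligand gene was 2.95, that of Ifnk, and near-identical Ifna genes may share the signal of Ifna4. A response to TPO itself, the difference between the groups, may account for the rise. The list and the comparison were fixed beforehand, but this was not tested in other data. The 10 splits of the 6 samples are too few for a share under 0.05.

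For the counts of genes, the real split gave 16 and the highest of the other splits 0, so that 1 of the 10 splits gave a count as large. For the counts of lists with the preset correlation, the real split gave 6 and the highest other 8, and 3 splits gave a count as large; among the 4 splits that part all pairs of a pool, the highest other was 5. With 10 splits neither count can be given a share under 0.05. The other splits with 8 and with 6 lists set both samples of pool 2 apart with the pool 4 sample without or with TPO, and the paired values are given with the results. The interferon median was 1.02 in the real split and at most 0.522 in size in the others. In camera with the preset correlation the interferon list had an adjusted p of 2.74e-57 in the real split. In the other splits it ran from 1.76e-11 to 0.167, and only the 0.167 lay above 0.05. Each other split still mixed the groups unevenly, so passing this test is not particular to the real split.

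The test of pool differences in the immediate early list was chosen after the result was seen. With all samples and genes the list passed only with pools paired (adjusted p = 0.00534), a call lost with an estimated correlation (adjusted p = 0.438), and it stood highest in both samples of pool 3. Differences between pools shared by both groups may have widened the unpaired spread: pools held 93.5% of the variance of the list's mean, more than in 92.88% of matched random lists, whose median was 69.8%, which falls short of the 95% set for this test and leaves it open. A shared handling response of stress genes, such as in sorting, is consistent with the heat shock and stress list, where pools held 97.3% of the variance, more than in 98.11% of matched lists (median 67.1%). No record of handling was analysed here, and a difference between the mice of each pool stays open as untested.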
